A study of Homo sapiens with 15 samples.

How the data were processed

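Gene expression was measured by RNA sequencing in human umbilical vein endothelial cells (HUVEC), primary cells that line the umbilical vein, taken from 2 cell isolates called isolate 1 and isolate 4. Per the labels' protocols, cells at passages 3 to 5 were held at 3% oxygen and moved to a low-serum medium with a 2% growth supplement before the experiment. They were given KU60019 at 5 µM, KU55933 at 10 µM or the vehicle DMSO for 8 h. Both compounds are inhibitors of the kinase ATM per the labels. Libraries were made from about 500 ng of RNA with a stranded kit that selects poly-A RNA, and were read as single 50 bp reads, per the labels' protocols; another label calls the assay total RNA-seq.

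The deposited values are estimated counts per gene symbol, with 1 column per library and no normalization. The submitters' processing notes name fastp 0.20.0, Salmon 0.14.1 and the build hg38, without saying what each did; the annotation and the way transcripts were summed to symbols are not given in the sources used here. Salmon's estimated counts share reads that fit several transcripts among them, so genes with near-identical copies carry an uncertainty that the replicates do not show. Transcript lengths per library were not used here, so a change in the isoforms of a gene can move its count without a change in the number of molecules.

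The table held 57224 symbols, 34965 of them with a count above 0 in some library. Of the symbols, 96.9% matched a gene name of GENCODE release 29, which gave positions on GRCh38 and the transcript length and GC content of each gene. Total counts per library ran from 28997597 to 45314737. Counts were simulated with the real means and library sizes and with 1 fitted spread per gene for all groups. The test recovered 82 of 100 genes changed 2-fold and 38 of 100 changed 1.5-fold for KU60019 in isolate 1, in a run on 16841 genes. The figures were 85 and 41 for KU60019 in isolate 4 on 16812 genes, and 75 and 49 for KU55933 in isolate 4 on 16792 genes. Between 5 and 7 unchanged genes were called in those runs. The runs do not carry the wider spread that KU60019 replicate 3 gives its group in isolate 4, so they do not describe that comparison fully. The fitted spread includes that library, so the runs may understate recovery at the spread of the other groups.

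Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with the filterByExpr function, which left 17150, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to the 15 libraries with 5 group means of 3 libraries each, which leaves 10 residual degrees of freedom, so that all groups share an estimate of the spread. The groups are not equally wide, as KU60019 replicate 3 of isolate 4 lies far from its partners. The p-values and standard errors are then likely too small in comparisons with that group and too large in the others. Every adjusted p given for a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes of the fit. The main fit has 17150 genes, and a gene is called when its adjusted p lies below 0.05. A fit without a library was filtered and scaled anew, which left 17614 genes without KU60019 replicate 3 of isolate 4. For a log2 fold change, an error after ± is an approximate standard error. It is the size of the change divided by the square root of the test's F statistic, and rests on the spread shared by all groups. For a level in normalised CPM, a gene's count scaled to a common library total, the error is an SD over 3 libraries. Intervals use the approximate standard error and have a confidence level of 95%. XIST and Y-linked genes were left out of every text and figure.

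The comparisons were KU60019 against DMSO in each isolate, KU55933 against DMSO in isolate 4, the difference of the KU60019 effect between isolates as an interaction, and KU55933 against KU60019 in isolate 4. Overlaps of calls in the same direction were set beside the number that independent lists would give. The isolate 4 comparisons share their 3 DMSO libraries, so 20 simulations of unchanged groups against those libraries gave the correlation and overlap that the shared controls produce with no effect. With 3 controls, no split leaves at least 2 libraries on each side.

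Before the data were examined, 23 gene lists with 575 members in total were fixed, covering pathways, endothelial functions and markers of other cell types, and 539 members could be tested; 6 members were found under an older symbol. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 23 lists of a comparison, then with an estimated correlation and with fry. The fry test asks whether the genes of a list move, on balance, in 1 direction, without comparing the list with other genes. Median, mean and camera's direction differed in sign only for lists that were not called, such as the interferon list with KU60019 in isolate 1 (median 0.04, mean 0.06, direction down). Adjusted p-values for lists come from camera with the preset correlation unless another is named. The rule for named genes took, for each inhibitor against DMSO, the 10 higher and 10 lower genes with the largest change among called genes with an average log2 CPM of at least 2 and no overlap between treated and control libraries. It took up to 5 in each direction for the other comparisons, up to 4 members of each list by adjusted p together with members called against the list's main direction, and ATM, ATR, PRKDC, MTOR and SMG1. Genes named outside that rule are marked as chosen after their values were seen.

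The alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 test, no filter on low counts, a fit with the compared groups only, the replicate number as a block, leaving out each library in turn, an estimated correlation and fry. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Those chosen only after the data were seen are the counts without KU60019 replicate 3 of isolate 4 in comparisons of other groups, in the members called per list and in the correlations between comparisons. All 15 libraries were used.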

Results

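Transcript levels were measured in HUVEC from 2 isolates to ask what inhibitors of ATM change in them. ATM is a kinase that signals DNA double-strand breaks and oxidative stress. Isolate 1 gave 3 libraries with DMSO and 3 with 5 µM KU60019; isolate 4 gave 3 libraries each with DMSO, 5 µM KU60019 and 10 µM KU55933. Treatment lasted 8 h throughout. Total counts per library were 28997597 to 45314737, mitochondrial transcripts made up 3.02% to 4.89% of them, and counts were tested for 17150 genes.

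The first principal component, with 41.8% of the variance, separated the isolates. The second, with 12.4%, set KU60019 replicate 3 of isolate 4 at -80.6, while the other 14 libraries lay between -16.3 and 27.3. Counts of that library differed from those of its 2 partners with a chi-square per degree of freedom of 161.76 and 147.11, against 4.10 to 28.41 for the other pairs within groups. No pair of replicates agreed within sampling noise. Its total of 33071731 counts lay inside the range of the others. The library was kept, and counts without it are given beside the main ones. Because all groups share an estimate of the spread, p-values are likely too small in comparisons with its group and too large in the others. Leaving it out was planned for the comparisons it belongs to, and was chosen after the data were seen for the other comparisons, for list members and for correlations between comparisons.

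**Figure D1:**
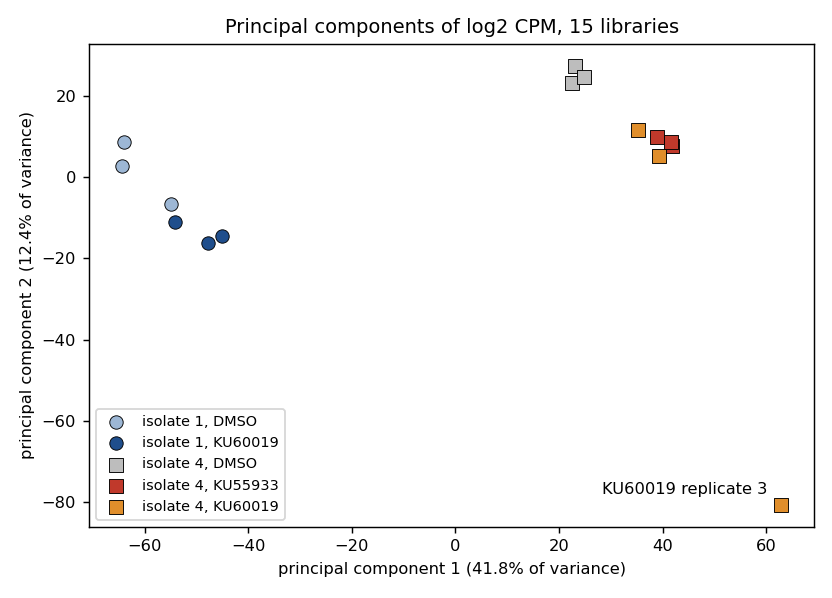
Principal component 1 (horizontal, 41.8% of variance) against component 2 (vertical, 12.4% of variance) of log2 CPM, with a point per library, circles for isolate 1 and squares for isolate 4. The isolates lie on opposite sides of component 1, and KU60019 replicate 3 of isolate 4 lies at -80.6 on component 2.

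ATM itself (GRCh38, chromosome 11, 108222484 to 108369102) was measured at 51.2 ± 4.92 CPM with DMSO and 49.1 ± 5.36 CPM with KU60019 in isolate 1. In isolate 4 it was at 44.1 ± 3.70 CPM with DMSO, 34.8 ± 15.6 CPM with KU60019 and 48.3 ± 5.16 CPM with KU55933, and no comparison called it. Among the related kinase genes, PRKDC, which encodes the catalytic subunit of DNA-PK, was lower with KU60019 in isolate 4 (log2 fold change -0.69 ± 0.16, adjusted p = 0.0112). PRKDC was not called in isolate 1 (-0.29 ± 0.16, adjusted p = 0.350) or with KU55933 (-0.40 ± 0.16, adjusted p = 0.122). ATR, MTOR and SMG1 were not called in any comparison; ATR came closest with KU60019 in isolate 4 (-0.72 ± 0.23, adjusted p = 0.0506). Without the library that stands apart, ATR was called lower in isolate 1 (-0.46, adjusted p = 9.88e-04), with KU60019 in isolate 4 (-0.41, adjusted p = 0.00615) and with KU55933 (-0.60, adjusted p = 5.02e-05). SMG1 was then called higher in the same comparisons (adjusted p = 0.00131, 0.00555 and 0.0147). The ATM value with KU60019 in isolate 4 was -0.34 ± 0.25 (adjusted p = 0.367) with that library and -0.02 (adjusted p = 0.951) without it.

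In isolate 1, KU60019 raised the adhesion genes ICAM1 and SELE and the cytochrome gene CYP1A1, and lowered the list of DNA replication genes. ICAM1, an adhesion receptor for leukocytes on endothelium (chromosome 19, 10270835 to 10286615), went from 8.76 ± 0.689 CPM with DMSO to 45.1 ± 4.54 CPM (n = 3 each). CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), went from 12.4 ± 1.19 to 64.5 ± 4.14 CPM. These rises of 5.16-fold and 5.21-fold are log2 fold changes of 2.37 ± 0.11 and 2.38 ± 0.10. The replicative helicase gene MCM4 (chromosome 8, 47960185 to 47978160) fell from 146 ± 8.19 to 68.0 ± 5.33 CPM. GJA5, which encodes an arterial gap junction protein (chromosome 1, 147756199 to 147773362), fell from 8.17 ± 0.274 to 1.92 ± 0.627 CPM.

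Of the 17150 genes, 487 were higher and 634 lower, 57 and 48 of them at least 2-fold, with a median size of 0.47 among the called genes. Among called genes with an average log2 CPM of at least 2 and no overlap between treated and control libraries, the largest rises besides ICAM1 and CYP1A1 were those of SELE, which encodes the adhesion molecule E-selectin (2.13 ± 0.28, adjusted p = 5.63e-04), and PLA2G4C (1.47 ± 0.14). They were followed by SNHG7 (1.31 ± 0.16), the polyamine oxidase gene SMOX (1.24 ± 0.12) and PPP1R15A, a regulator of translation under stress (1.21 ± 0.11). OSGIN1, RELB and PRX came next, with values of 1.19, 1.17 and 1.13. The largest fall among such genes was that of TGFB2, a ligand of the transforming growth factor beta family (-2.42 ± 0.45, adjusted p = 0.00603). It was followed by those of GJA5 (-2.09 ± 0.26), FAM111B (-1.26 ± 0.14), ZNF367 (-1.22 ± 0.22), CDCA7 (-1.21 ± 0.09), MAP2K6 (-1.18 ± 0.18), NEXN (-1.17 ± 0.14), UHRF1 (-1.15 ± 0.10) and CCDC190 (-1.13 ± 0.16).

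By list, 23 of 28 DNA replication and E2F target genes fell and 0 rose (25 lower adjusted over the list alone; median -0.70, adjusted p = 3.30e-29). Among them were MCM4 (-1.10 ± 0.08), MCM6 (-1.09 ± 0.09) and MCM3 (-0.76 ± 0.09), all subunits of the same helicase. Of the ATF4 and amino acid response list, 14 of 30 rose and 0 fell (19 higher adjusted over the list alone; median 0.41, adjusted p = 4.22e-16). They included the asparagine synthetase gene ASNS (1.11 ± 0.09), the serine synthesis gene PSAT1 (0.56 ± 0.07) and ATF4 itself (0.93 ± 0.12). Cholesterol synthesis genes rose in 11 of 24 cases with 0 lower (14 higher adjusted over the list alone; adjusted p = 6.70e-11), such as INSIG1 (0.78 ± 0.09) and MVK (0.72 ± 0.14). Glutamine and nucleotide synthesis genes fell in 11 of 26 cases with 0 higher (13 lower and 1 higher adjusted over the list alone; adjusted p = 5.52e-08). The smallest adjusted p-values were those of the purine synthesis genes PAICS (-0.61 ± 0.06) and GMPS (-0.53 ± 0.08), then CTPS1 (-0.54 ± 0.08).

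NF-kB inflammatory genes rose in 7 of 23 cases with 0 lower (8 higher and 2 lower adjusted over the list alone; adjusted p = 1.44e-04). Lysosome and autophagy genes rose in 6 of 32 cases with 0 lower (11 higher adjusted over the list alone; adjusted p = 1.88e-06), with GABARAPL1 at 0.94 ± 0.07 and SQSTM1 at 0.91 ± 0.10. Heat shock and chaperone genes fell in 9 of 25 cases with 0 higher (9 lower adjusted over the list alone; adjusted p = 1.28e-05), including HSPD1 (-0.41 ± 0.06) and HSPA8 (-0.34 ± 0.07). These 7 lists stayed called in camera with an estimated correlation, at the much weaker adjusted p = 0.00494 to 0.0334.

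The calls of 6 further lists were lost with an estimated correlation. DNA damage sensing and repair genes fell in 5 of 32 cases (9 adjusted over the list alone; adjusted p = 2.56e-08, but adjusted p = 0.0785 with an estimated correlation). PARP1 (-0.52 ± 0.07) and XRCC5 (-0.36 ± 0.06) were among them. G2 and mitosis genes fell in 4 of 25 cases (11 adjusted over the list alone), namely CCNA2, KIF20A, TPX2 and CDK1 (adjusted p = 3.21e-07, but adjusted p = 0.0679 with an estimated correlation). Of 19 FOXO targets TXNIP (0.69 ± 0.08) and BCL2L11 (0.78 ± 0.13) rose and SESN1 fell (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00149, but adjusted p = 0.424 with an estimated correlation). Of 25 NRF2 antioxidant targets OSGIN1 and HMOX1 (0.62 ± 0.11) rose (2 higher adjusted over the list alone; adjusted p = 0.00758, but adjusted p = 0.191 with an estimated correlation). Of 29 mitochondrial genes CYCS (-0.46 ± 0.08), PPARGC1B and TFAM fell (4 lower adjusted over the list alone; adjusted p = 0.0367, but adjusted p = 0.495 with an estimated correlation). That call was also lost without DMSO replicate 2 or 3 or KU60019 replicate 2 of isolate 1. Of 23 immediate early and MAPK feedback genes 4 rose, among them DUSP4 (0.48 ± 0.06), and CCND1 fell (-0.69 ± 0.09), with 5 and 1 adjusted over the list alone. This list had adjusted p = 0.00303 (but adjusted p = 0.129 with an estimated correlation). Without KU60019 replicate 3 of isolate 4, the members higher and lower were 0 and 17 for repair, 0 and 15 for mitosis, 6 and 1 for FOXO and 8 and 0 for NRF2. They were 0 and 7 for the mitochondrial list, 8 and 1 for MAPK, 12 and 0 for lysosome, 8 and 2 for NF-kB and 2 and 14 for glutamine and nucleotide synthesis.

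The remaining 10 lists were not called. The p53 targets had 3 members higher and 2 lower of 30 (3 and 3 adjusted over the list alone; adjusted p = 0.490). In that list GDF15 (1.00 ± 0.17) and the cell cycle inhibitor gene CDKN1A (0.50 ± 0.11) rose, while MDM2 (-0.48 ± 0.13) and SESN1 (-0.49 ± 0.11) fell. In the endothelial identity list (adjusted p = 0.754) KLF4 rose (0.70 ± 0.12) and EMCN fell (-0.59 ± 0.11). The interferon list had 3 members higher and 2 lower of 27 (4 and 6 adjusted over the list alone; adjusted p = 0.830), with GBP1 lower (-1 ± 0.12). The glycolysis and hypoxia list had 3 and 2 of 27 (3 and 2 adjusted over the list alone; adjusted p = 0.169), with NDRG1 higher (0.54 ± 0.08). The Notch and sprouting list had 2 and 5 of 24 (3 and 7 adjusted over the list alone; adjusted p = 0.131), with GJA5 lower and CXCR4 higher (0.69 ± 0.08). The fry test called the Notch and sprouting list lower (adjusted p = 0.0307). In the TGF-beta and BMP list (adjusted p = 0.145) TGFB2 and BMP4 (-0.38 ± 0.08) fell, and in the peroxide and superoxide removal list (adjusted p = 0.401) GPX8 fell (-0.29 ± 0.07). The called members of the endothelial identity, TGF-beta and BMP, and peroxide lists numbered 2, 3 and 1, and as many adjusted over the list alone. Of the markers of other cell types, the smallest adjusted p among 11 smooth muscle and fibroblast genes was that of COL1A2 (-0.29 ± 0.10, adjusted p = 0.116). Among 6 leukocyte and red cell genes it was that of LAPTM5 (-0.16 ± 0.08, adjusted p = 0.265) and among 5 lymphatic genes that of FLT4 (-0.29 ± 0.10, adjusted p = 0.117). KU60019 replicate 3 of isolate 4 enters this comparison only through the shared spread, the filter and the scaling. Without it 1546 genes were higher and 2153 lower, and all 1121 calls were found again in the same direction. The members higher and lower were then 6 and 9 for p53, 2 and 5 for endothelial identity, 4 and 6 for interferon, 6 and 4 for glycolysis, 3 and 7 for Notch, 1 and 4 for TGF-beta and 1 and 4 for peroxide removal. Of the markers, 1 lymphatic gene was higher and 2 were lower, and 1 smooth muscle gene was lower. Leaving out DMSO replicate 1 or 2 of isolate 1 gave 236 and 205 higher and 351 and 269 lower genes. Leaving out KU60019 replicate 1, 2 or 3 of isolate 1 gave 273, 187 and 254 higher and 336, 203 and 344 lower.

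In isolate 4, KU60019 also raised ICAM1, SELE and CYP1A1, and lowered the lists of replication and mitosis genes. ICAM1 rose from 31.1 ± 0.968 to 166 ± 14 CPM (2.42 ± 0.10) and CYP1A1 from 14.7 ± 1.11 to 56.8 ± 2.90 CPM (1.95 ± 0.10), n = 3 each. F2RL3, which encodes a thrombin receptor, rose from 4.15 ± 0.153 to 20.3 ± 4.02 CPM (2.29 ± 0.13). TGFB2 fell from 35.1 ± 1.45 to 9.57 ± 3.32 CPM (-1.87 ± 0.30) and MCM4 from 100 ± 6.26 to 46.3 ± 3.09 CPM. The test called 1386 genes higher and 1418 lower, 164 and 157 of them at least 2-fold, with a median size of 0.52.

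Further rises, at an average log2 CPM of at least 2, were those of PLA2G4C (1.95 ± 0.13), RASD1 (1.82 ± 0.15), SELE (1.77 ± 0.23), RELB, a subunit of NF-kB (1.73 ± 0.20), ISG20 (1.70 ± 0.20), SMOX (1.62 ± 0.13) and ASNS (1.5 ± 0.09). DACH1 (-1.74 ± 0.16), FRMD3 (-1.67 ± 0.13), CCBE1 (-1.66 ± 0.14), CDCA7 (-1.64 ± 0.09), GJA5 (-1.63 ± 0.25), NEXN (-1.59 ± 0.14), ZNF367 (-1.55 ± 0.23) and SEMA3D, which encodes a secreted guidance protein (-1.49 ± 0.29), fell. HSP90AA6P had the largest fitted fall at that average level (-2.86 ± 0.55), but it is a pseudogene whose reads can be shared with HSP90AA1 and its level in isolate 4 was below 1 CPM, so its value is uncertain.

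Of the DNA replication and E2F targets, 22 of 28 fell and 0 rose (24 lower adjusted over the list alone; median -0.62, adjusted p = 6.79e-16). Of the G2 and mitosis genes 21 of 25 fell and 0 rose (21 lower adjusted over the list alone; median -0.52, adjusted p = 1.55e-11). UHRF1, a maintenance factor of DNA methylation, fell by 1.31 ± 0.10 on the log2 scale, MCM10 by 1.16 ± 0.10, the mitotic kinesin gene KIF20A by 0.81 ± 0.09 and the mitotic cyclin gene CCNB1 by 0.56 ± 0.09. The ATF4 list had 15 of 30 members higher and 0 lower (19 higher and 3 lower adjusted over the list alone; adjusted p = 3.64e-09), with ASNS, PCK2 (1.27 ± 0.13) and ATF4 (1.15 ± 0.12). Glutamine and nucleotide synthesis genes fell in 13 of 26 cases (13 adjusted over the list alone; adjusted p = 2.32e-06). PAICS (-0.76 ± 0.06) and PFAS (-0.81 ± 0.08) were among them, while GLUL, which encodes glutamine synthetase, rose (0.33 ± 0.08). Lysosome and autophagy genes rose in 13 of 32 cases (14 adjusted over the list alone; adjusted p = 1.85e-05), with GABARAPL1 at 1.25 ± 0.07, SQSTM1 at 1.17 ± 0.10 and only UVRAG lower (-0.31 ± 0.08). Those 5 lists stayed called in camera with an estimated correlation, at the much weaker adjusted p = 0.0315, or 0.0465 for the lysosome and autophagy list.

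NF-kB inflammatory genes went both ways, with 9 of 23 higher and 5 lower (10 and 5 adjusted over the list alone; adjusted p = 0.0403, but adjusted p = 0.231 with an estimated correlation). ICAM1, SELE, RELB and the chemokine gene CX3CL1 (2.76 ± 0.24) rose. The neutrophil chemokine genes CXCL1 (-1.05 ± 0.11) and CXCL8 (-0.81 ± 0.11), together with IL6 (-0.60 ± 0.15), NFKB1 (-0.25 ± 0.07) and TNFAIP3 (-0.55 ± 0.17), fell. The calls of 4 more lists were lost with an estimated correlation. Cholesterol synthesis genes rose in 6 of 24 cases, led by INSIG1 (0.55 ± 0.09), with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0106, but adjusted p = 0.143 with an estimated correlation). DNA damage sensing and repair genes fell in 10 of 32 cases, with 14 lower adjusted over the list alone (adjusted p = 1.28e-06, but adjusted p = 0.167 with an estimated correlation). PARP1 (-0.55 ± 0.07) and MRE11 (-0.56 ± 0.10) were among them. Heat shock and chaperone genes fell in 8 of 25 cases (9 adjusted over the list alone), among them HSPD1 at -0.46 ± 0.06 (adjusted p = 0.00996, but adjusted p = 0.197 with an estimated correlation). Of 25 NRF2 targets 5 rose, led by HMOX1 (1.20 ± 0.11), and ME1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0218, but adjusted p = 0.276 with an estimated correlation). The remaining 13 lists were not called. The p53 targets had 6 of 30 members higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.641), with GDF15 (1.45 ± 0.17) and CDKN1A (0.76 ± 0.11) higher. In the other lists CCND1, a cyclin of the G1 phase, fell (-1.15 ± 0.09), EGR1 (1.26 ± 0.14) and the chemokine receptor gene CXCR4 (1.25 ± 0.08) rose, and BMP4 fell (-1.04 ± 0.08).

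The library that stands apart belongs to this group, and without it 1585 genes were higher and 1879 lower, with 2379 of the 2804 calls found again and 0 in the opposite direction. The list counts without it were 0 higher and 24 lower for replication, 0 and 22 for mitosis, 18 and 3 for ATF4. They were 2 and 14 for glutamine and nucleotide synthesis, 14 and 1 for lysosome, 9 and 4 for NF-kB, 10 and 1 for cholesterol synthesis and 5 and 0 for NRF2. The endothelial identity list had 6 higher and 1 lower member with it and 4 and 4 without it, the FOXO list 4 and 1 with it and 9 and 1 without it, and the p53 list 6 and 2 without it. Without it the FOXO (adjusted p = 9.11e-06), mitochondrial (adjusted p = 0.00465) and TGF-beta lists (adjusted p = 0.0187) were called too, with the preset correlation. The heat shock list lost its call without KU60019 replicate 1 or 2, and the NF-kB list without replicate 2. RGS5 was the only marker of smooth muscle and fibroblasts called (-0.44 ± 0.14, adjusted p = 0.0497). With the 6 libraries of the comparison alone in the fit, 131 genes were higher and 155 lower, and leaving out DMSO replicate 1, 2 or 3 gave 656, 763 and 668 higher and 775, 928 and 803 lower. Leaving out KU60019 replicate 1 gave 2279 and 2161.

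**Figure D2:**
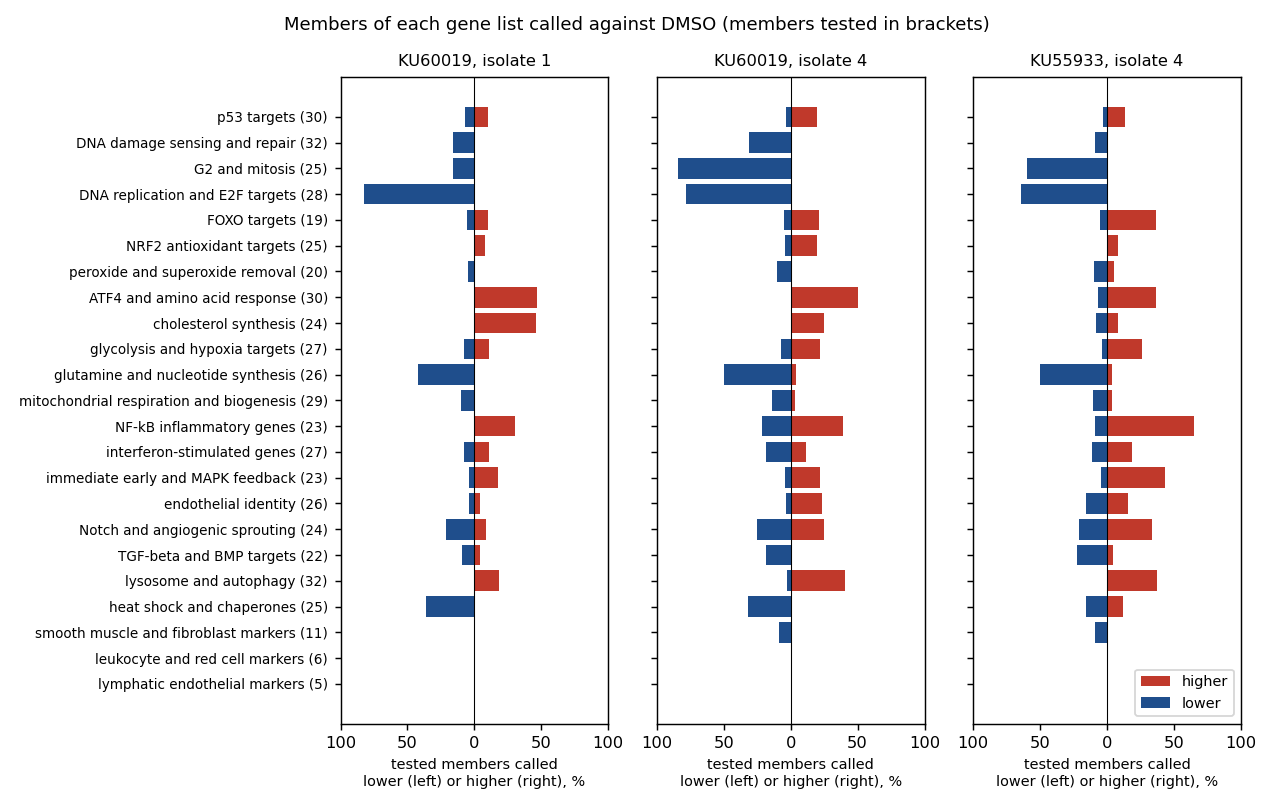
Share of the tested members of each of 23 gene lists called higher (red, to the right) or lower (blue, to the left), in percent, for each inhibitor against DMSO; the number of members tested stands in brackets. Replication genes fell in 23, 22 and 18 of 28 cases, and NF-kB genes rose in 7, 9 and 15 of 23.

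The repeat of KU60019 in a second isolate asks whether the isolates respond alike. ICAM1 and SELE rose in both, and the replication list (lower) and the ATF4 list (higher) were called in both, also with an estimated correlation. In all, 395 genes were called higher in both isolates and 517 lower in both, and 0 went in opposite directions, where independent lists would share 39.4 and 52.4. Across genes, which are not independent replicates, the fold changes had r = 0.29 and rho = 0.53. The isolates have separate controls, so no library enters both fold changes. Both tests take the spread of each gene from the same fit to all libraries, so their calls are not fully independent. ICAM1, CYP1A1, SELE, PLA2G4C, SMOX, RELB, TGFB2, GJA5, CDCA7, NEXN and ZNF367 were among the largest changes in both at an average log2 CPM of at least 2. When KU60019 replicate 3 of isolate 4 was left out, 1009 genes were higher and 1366 lower in both, with 3 in opposite directions. Leaving out DMSO replicate 1 or 2 of isolate 1 gave 197 and 187 higher and 326 and 243 lower, and leaving out DMSO replicate 1 of isolate 4 gave 255 higher. Leaving out KU60019 replicate 1, 2 or 3 of isolate 1 gave 235, 167 and 223 higher and 299, 189 and 306 lower.

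The difference of the effect itself, tested as an interaction, called 7 genes. F2RL3 rose more in isolate 4, by 2.29 ± 0.13 against 0.95 ± 0.15 in isolate 1 (difference 1.34 ± 0.20, adjusted p = 0.0388). The effect was lower in isolate 4 than in isolate 1 for the matricellular genes CCN2 (-0.61 ± 0.07, adjusted p = 0.0116) and CCN1 (-0.57 ± 0.09, adjusted p = 0.0388) and for ANKRD1 (-0.83 ± 0.10, adjusted p = 0.0116). It was also lower for the Wnt antagonist gene DKK1 (-0.79 ± 0.11, adjusted p = 0.0274) and the chemokine genes CXCL1 (-1.11 ± 0.17, adjusted p = 0.0388) and CXCL8 (-1.01 ± 0.16, adjusted p = 0.0403). At an unadjusted p under 0.05 the count was 777 genes, and the DESeq2 test called 12 higher and 20 lower. Of the lists, G2 and mitosis (median -0.25, adjusted p = 3.39e-08, but adjusted p = 0.144 with an estimated correlation) and cholesterol synthesis (median -0.18, adjusted p = 2.70e-04, but adjusted p = 0.133 with an estimated correlation) lay lower in isolate 4. KIF20A (-0.46 ± 0.12, adjusted p = 0.653) and MSMO1 (-0.27 ± 0.10, adjusted p = 0.906) had the smallest adjusted p of their lists. Without KU60019 replicate 3 of isolate 4, 11 genes were higher and 22 lower, all 7 included, and the p53 list was called as well with the preset correlation (median 0.12, adjusted p = 0.00266). Leaving out any other library gave 0 to 1 higher and 0 to 3 lower; a fit to the 12 libraries of these groups in edgeR called 0.

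KU55933 in isolate 4 raised the lists of NF-kB inflammatory and immediate early genes, and lowered those of replication and mitosis and the connexin genes GJA5 and GJA4. ICAM1 rose from 31.1 ± 0.968 to 234 ± 23.1 CPM (2.91 ± 0.10) and SELE from 4.96 ± 0.227 to 33.0 ± 4.27 CPM (2.73 ± 0.23), n = 3 each. GJA5 fell from 10.7 ± 1.08 to 1.61 ± 0.770 CPM (-2.75 ± 0.27) and GJA4, which encodes connexin 37, from 11.7 ± 0.670 to 1.86 ± 0.144 CPM (-2.65 ± 0.20). The test called 1062 genes higher and 1226 lower, 161 and 149 of them at least 2-fold, with a median size of 0.51.

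F2RL3 (2.43 ± 0.13), RASD1 (2.37 ± 0.15), RELB (2.33 ± 0.20), the stress cytokine gene GDF15 (2.22 ± 0.17) and PLA2G4C (2.01 ± 0.13) rose, as did the heme oxygenase gene HMOX1 (1.87 ± 0.12), the prostaglandin synthase gene PTGS2 (1.83 ± 0.24) and CYP26B1 (1.83 ± 0.19). TNFSF18 (-2.07 ± 0.10), DACH1 (-1.93 ± 0.17), TGFB2 (-1.81 ± 0.30), CCDC190 (-1.75 ± 0.16), RGS4 (-1.58 ± 0.11), CDCA7 (-1.57 ± 0.09), PRICKLE1 (-1.54 ± 0.13) and PTX3 (-1.54 ± 0.08) fell.

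NF-kB inflammatory genes rose in 15 of 23 cases and fell in 2 (17 and 3 adjusted over the list alone; median 1.11, adjusted p = 2.68e-11). CX3CL1 rose by 3.03 ± 0.24, and IL6 (-0.82 ± 0.15) and CXCL1 (-0.43 ± 0.11) fell. Replication and E2F targets fell in 18 of 28 cases (20 lower and 1 higher adjusted over the list alone; median -0.55). G2 and mitosis genes fell in 15 of 25 (18 adjusted over the list alone; median -0.41), and both lists had adjusted p = 6.55e-13. UHRF1 (-1.30 ± 0.10), MCM4 (-0.90 ± 0.08), CDC20, an activator of the anaphase-promoting complex (-1.09 ± 0.14), and CCNB1 (-0.80 ± 0.09) were among them. Glutamine and nucleotide synthesis genes fell in 13 of 26 cases (17 adjusted over the list alone; adjusted p = 1.94e-08), including ATIC (-0.78 ± 0.11) and UMPS (-0.58 ± 0.08). Lysosome and autophagy genes rose in 12 of 32 cases (13 adjusted over the list alone; adjusted p = 5.22e-07), led by SQSTM1 (1.45 ± 0.10) and GABARAPL1 (1.13 ± 0.07). Immediate early and MAPK feedback genes rose in 10 of 23 (12 adjusted over the list alone; adjusted p = 3.96e-06), with EGR1 at 1.46 ± 0.14 and CCND1 lower (-1.09 ± 0.09). These 6 lists stayed called in camera with an estimated correlation, at the much weaker adjusted p = 0.00513 to 0.0364.

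The ATF4 list had 11 of 30 members higher and 2 lower (14 and 5 adjusted over the list alone; adjusted p = 3.41e-04, but adjusted p = 0.15 with an estimated correlation). Its stress genes ATF3 (2.41 ± 0.24) and DDIT3 (1.26 ± 0.16) rose, while PSAT1 (-0.30 ± 0.07) and STC2 (-0.28 ± 0.07) fell. FOXO targets rose in 7 of 19 cases, among them the proapoptotic gene BCL2L11 (1.36 ± 0.13), while TXNIP, an inhibitor of thioredoxin, fell (-0.86 ± 0.08). The counts were 9 and 1 adjusted over the list alone (adjusted p = 5.88e-04, but adjusted p = 0.363 with an estimated correlation). Glycolysis and hypoxia targets rose in 7 of 27 cases, led by NDRG1 (0.76 ± 0.08), and LDHA fell, with 9 and 1 adjusted over the list alone (adjusted p = 0.0369, but adjusted p = 0.357 with an estimated correlation). The NRF2 targets HMOX1 and FTH1 (0.54 ± 0.14) rose among 25 (2 adjusted over the list alone; adjusted p = 0.0482, but adjusted p = 0.357 with an estimated correlation). Of 32 repair genes PARP1 (-0.55 ± 0.07), XRCC5 and XRCC4 fell (3 adjusted over the list alone; adjusted p = 0.00283, but adjusted p = 0.357 with an estimated correlation). The glycolysis list lost its call without KU60019 replicate 3 (adjusted p = 0.0624), DMSO replicate 2 or KU55933 replicate 2, and the NRF2 list without DMSO replicate 2 or KU55933 replicate 1. Heat shock and chaperone genes were not called as a list, with 3 of 25 higher and 4 lower. HSPA6, an inducible HSP70 gene, was at 0.257 ± 0.0847 CPM with DMSO and 12.7 ± 5.39 CPM with KU55933 (5.62 ± 0.42), and HSPA8 fell (-0.50 ± 0.07).

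The p53 targets were not called as a list, with 4 of 30 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.105), while fry, which compares with no other genes, gave adjusted p = 2.82e-04 towards higher. CDKN1A stood at 0.78 ± 0.11. Cholesterol synthesis had 2 higher and 2 lower members of 24 (adjusted p = 0.646), with INSIG1 up (0.66 ± 0.09) and ACAT2 down (-0.50 ± 0.08). The endothelial identity list was split as well (4 and 4 of 26, adjusted p = 0.721), with KLF4 higher (1.09 ± 0.12) and the thrombomodulin gene THBD lower (-0.62 ± 0.08). Of the markers of other cell types, COL1A2 was called lower (-0.39 ± 0.09, adjusted p = 0.0121) among 11 smooth muscle and fibroblast genes. Camera did not call that list (adjusted p = 0.173), whereas fry called it lower (adjusted p = 0.0426). The smallest adjusted p was 0.135 among 6 leukocyte and red cell markers (FCER1G, 0.82 ± 0.34) and 0.223 among 5 lymphatic markers (PROX1, 0.66 ± 0.33). KU60019 replicate 3 of isolate 4 touches this comparison only through the shared spread, the filter and the scaling. Without it 2477 genes were higher and 2648 lower, and 2287 of the 2288 calls were found again. The list counts without it were 0 higher and 9 lower for repair, 0 and 23 for mitosis, 1 and 23 for replication, 17 and 6 for ATF4 and 16 and 0 for lysosome. They were 9 and 3 for p53, 7 and 0 for NRF2, 9 and 6 for glycolysis, 6 and 3 for cholesterol synthesis, 7 and 7 for endothelial identity and 6 and 7 for heat shock, and 2 smooth muscle markers were lower and 1 lymphatic marker higher. The 6 compared libraries alone gave 3034 and 3235. Leaving out DMSO replicate 1, 2 or 3 gave 586, 671 and 574 higher and 748, 853 and 739 lower, and leaving out KU55933 replicate 2 or 3 gave 618 and 610 higher and 712 and 750 lower.

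Set beside each other in isolate 4, KU60019 at 5 µM and KU55933 at 10 µM called 676 genes higher and 824 lower in both, and 5 in opposite directions; independent lists would share 85.8 and 101.4. The 5 are CYP26B1, CXCL8 and LPCAT1, lower with KU60019 and higher with KU55933, and PSAT1 and TXNIP, which went the other way; LPCAT1 was chosen after its values were seen. Across genes the fold changes had r = 0.61 and rho = 0.67. Simulated unchanged groups against the same 3 DMSO libraries gave a mean r of 0.50, at most 0.55, and 0 genes called in both. The covariance was 0.2425, against a simulated mean of 0.0758, a difference of 0.1667. With no effect simulated, few calls arise at all, so the 0 does not measure what shared controls add to the overlap of real effects. The simulated spread came from the fit to all libraries, so the simulated r and covariance may be too high. Part of the excess overlap may come from the shared controls. KU60019 in isolate 1 shares no control with KU55933 in isolate 4. These comparisons shared 320 higher and 475 lower genes and had 3 in opposite directions (LPCAT1, PSAT1 and TXNIP). Independent lists would share 30.2 and 45.3, and the fold changes had r = 0.21 and rho = 0.51. The spread of each gene came from the same fit in both, so the calls are not fully independent. Without KU60019 replicate 3 of isolate 4, the inhibitors shared 1246 higher and 1560 lower genes in isolate 4, with 12 in opposite directions. Leaving out DMSO replicate 1, 2 or 3 gave 348, 398 and 339 higher and 471, 547 and 471 lower, and leaving out KU55933 replicate 2 or 3 gave 421 and 412 higher and 535 and 547 lower.

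**Figure D3:**
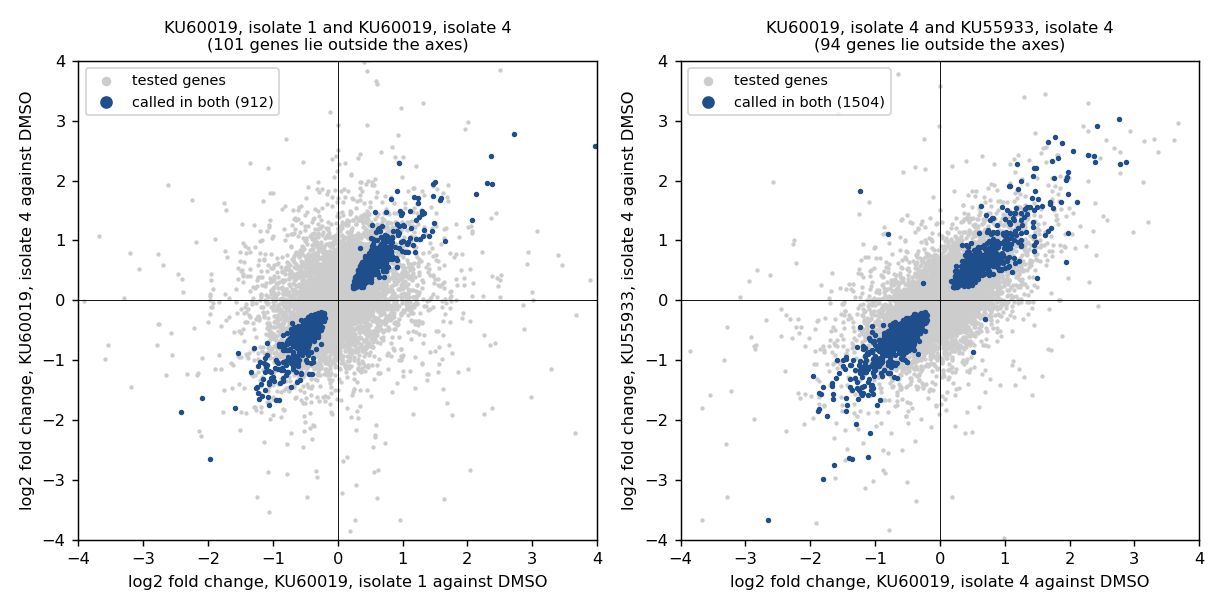
Log2 fold changes against DMSO of the tested genes other than XIST and Y-linked genes (grey), and of those called in both comparisons (blue). On the left is KU60019 in isolate 1 (horizontal) and isolate 4 (vertical). On the right are KU60019 (horizontal) and KU55933 (vertical) in isolate 4. Called genes lie along the diagonal, with 0 and 5 of them in opposite directions, and 101 and 94 genes lie outside the axes, which end at -4 and 4.

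Compared directly, KU55933 and KU60019 differed in the list of NF-kB inflammatory genes and in single genes such as CYP26B1, TXNIP and HSPA6. CYP26B1, an enzyme that degrades retinoic acid (chromosome 2, 72129238 to 72148038), was at 46.4 ± 10.8 CPM with KU55933 and 5.52 ± 1.24 CPM with KU60019, against 13.1 ± 0.518 CPM with DMSO. The difference was 3.07 ± 0.20 (adjusted p = 3.14e-06). TXNIP (chromosome 1, 145992435 to 145996600) was at 26.3 ± 1.39 and 67.9 ± 6.10 CPM, against 47.7 ± 1.08 CPM with DMSO, a difference of -1.37 ± 0.08 (adjusted p = 7.77e-07). Both genes changed in opposite directions from DMSO. CXCL8 did too, at 77.7 ± 5.93 and 20.5 ± 2.02 CPM against 35.9 ± 1.57 CPM with DMSO (difference 1.92 ± 0.11).

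In all, 59 genes were higher and 53 lower with KU55933 than with KU60019; doses differed between the compounds and the time was the same. DHRS3 (1.33 ± 0.20) and PTGS2 (1.27 ± 0.23) were higher, as was the readthrough gene SLX1A-SULT1A3 (1.13 ± 0.24, adjusted p = 0.05 after rounding), whose reads overlap near-identical neighbours and are uncertain. CYP1A1 (-1.30 ± 0.10), GJA4 (-1.30 ± 0.20), ASNS (-1.13 ± 0.09) and SEMA6A (-1.03 ± 0.15) were lower. NF-kB genes were higher with KU55933 in 6 of 23 cases and lower in 0 (14 higher adjusted over the list alone; adjusted p = 1.53e-13, and adjusted p = 0.00216 with an estimated correlation). Among them were BIRC3 (2.06 ± 0.31), IRF1 (0.76 ± 0.10) and CXCL3 (1.51 ± 0.26). The ATF4 list had 5 of 30 members lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 2.87e-05, but adjusted p = 0.0996 with an estimated correlation). PSAT1 stood at -1.01 ± 0.07, PCK2 at -0.97 ± 0.12 and ATF3 at 1.76 ± 0.23. Heat shock genes were higher in 3 of 25 cases and lower in 0 (6 higher adjusted over the list alone; adjusted p = 2.34e-04, but adjusted p = 0.0996 with an estimated correlation). They are HSPA6 (6.59 ± 0.46), HSP90AA1 (0.52 ± 0.08) and HSPH1 (0.49 ± 0.09). Immediate early and MAPK feedback genes were higher in 3 of 23 cases (8 adjusted over the list alone; adjusted p = 5.38e-06, but adjusted p = 0.0743 with an estimated correlation), including DUSP6 (0.50 ± 0.07).

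The cholesterol synthesis list lay lower with KU55933 (adjusted p = 0.00241, but adjusted p = 0.0996 with an estimated correlation). Higher with KU55933 lay the DNA repair list (adjusted p = 0.00241, but adjusted p = 0.374 with an estimated correlation) and the replication list (adjusted p = 0.00143, but adjusted p = 0.365 with an estimated correlation). So did the FOXO (adjusted p = 0.00271, but adjusted p = 0.473 with an estimated correlation) and interferon lists (adjusted p = 0.0196, but adjusted p = 0.124 with an estimated correlation). Without KU60019 replicate 3 the repair and FOXO lists lost their calls (adjusted p = 0.129 and 0.398), with medians of 0.02 and 0.03 against 0.15 and 0.17. The interferon list lost its call without KU60019 replicate 1 or 2 or KU55933 replicate 2. Some of the genes changed by both compounds were not called between them. The interval of the difference was -0.21 to 0.22 for UHRF1, -0.11 to 0.25 for MCM6, -0.22 to 0.16 for KIF20A, -0.12 to 0.26 for CCND1, -0.13 to 0.28 for CDCA7 and -0.58 to 0.71 for TGFB2. It was -0.20 to 0.34 for PLA2G4C, -0.12 to 0.41 for F2RL3, -0.27 to 0.03 for GABARAPL1 and -0.18 to 0.16 for BMP4. Other intervals left out 0 without a call after adjustment: 0.25 to 0.85 for RASD1, 0.41 to 1.12 for GDF15, 0.21 to 0.99 for RELB, 0.08 to 0.49 for SQSTM1, 0.04 to 0.40 for MCM4 and 0.03 to 0.29 for PAICS. The same holds for GJA5 (-1.71 to -0.54), CDC20 (-0.68 to -0.10), CCNB1 (-0.44 to -0.06) and PTX3 (-0.50 to -0.16), and the smallest adjusted p of these 10 was 0.0598. ICAM1 was higher with KU55933 (0.49 ± 0.10, adjusted p = 0.0357), whereas SELE was not called (0.96 ± 0.21, interval 0.50 to 1.42, adjusted p = 0.0648). Of these genes, those that the naming rule does not give for this comparison were chosen after their values were seen. With KU60019 replicate 3 left out, 177 genes were higher and 152 lower, including 110 of the 112 calls, and the NF-kB list had 9, the MAPK list 6 and the replication list 3 higher members, the heat shock list 4 higher and 1 lower. The p53 (adjusted p = 0.0352), glycolysis (adjusted p = 1.20e-04), endothelial identity (adjusted p = 0.0139) and lysosome lists (adjusted p = 0.0279) were then called too, with the preset correlation. A fit to these 6 libraries alone called 3 and 3, and leaving out KU55933 replicate 1, 2 or 3 gave 23, 15 and 24 higher and 18, 9 and 15 lower.

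**Figure D4:**
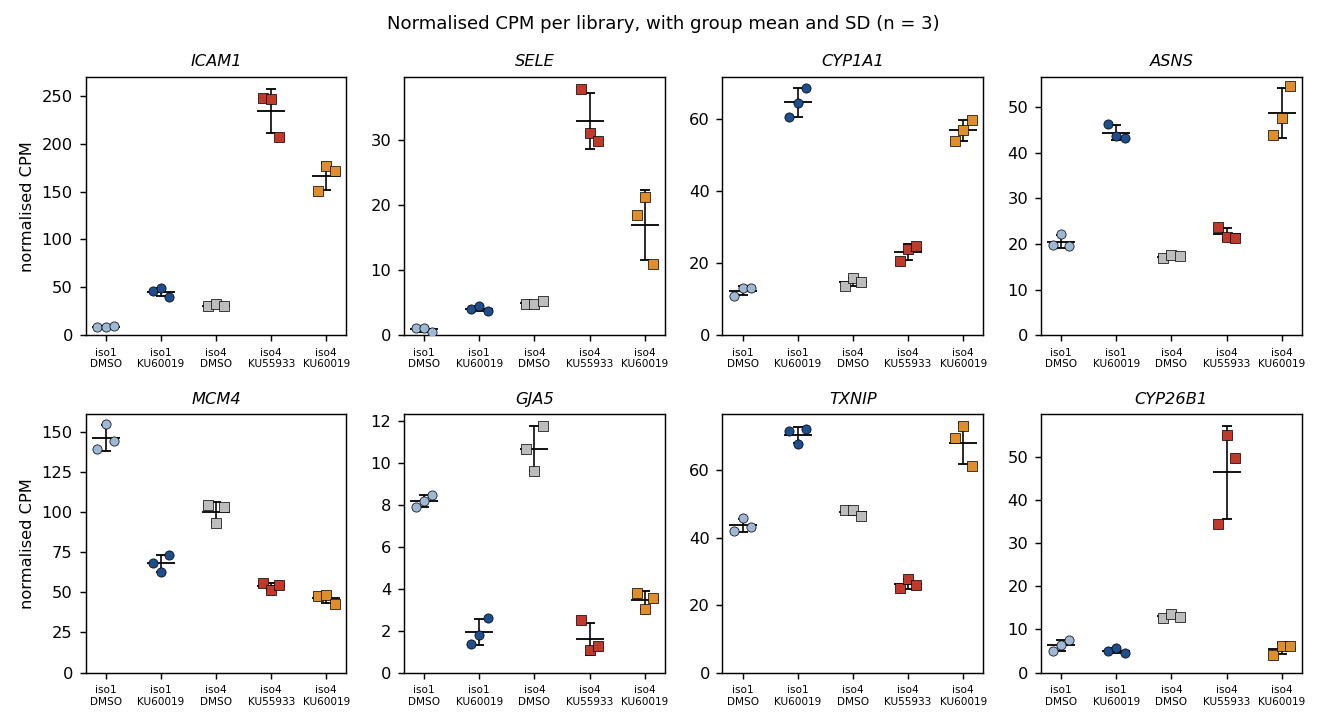
Normalised CPM (vertical, from 0) of 8 genes in each of the 15 libraries, by group, with the group mean and SD (n = 3) as black lines. ICAM1 and SELE are higher than with DMSO, and MCM4 and GJA5 lower, with KU60019 in both isolates and with KU55933 in isolate 4, and TXNIP and CYP26B1 move in opposite directions with the 2 inhibitors in isolate 4.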

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

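The tests of why KU60019 replicate 3 of isolate 4 stands apart were all chosen only after the result was seen. The effect of KU60019 differed between the isolates, in a test of the difference itself, for 7 genes.

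The thrombin receptor gene F2RL3 rose more in isolate 4 than in isolate 1, with a difference of 1.34 in the log2 effect. For the matricellular genes CCN2 and CCN1 the difference was -0.61 and -0.57, with effects of 0.00 and -0.10 in isolate 1 and of -0.61 and -0.67 in isolate 4. For ANKRD1 and DKK1 it was -0.83 and -0.79, both lower in each isolate. The chemokine genes CXCL1 and CXCL8 differed by -1.11 and -1.01, and fell in isolate 4 alone by the test, with values of 0.06 and 0.20 in isolate 1. The G2 and mitosis list differed by a median of -0.25 and the cholesterol synthesis list by -0.18, but neither list stayed called with an estimated correlation (adjusted p = 0.144 and 0.133) and fry called 0 lists.

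Of 100 splits of the 12 libraries, 7 gave at least the 7 genes of the real split, and the highest of the others gave 2040. Those with at least 7 genes were the real split and 6 of the 23 drawn splits that kept the treatment groups of 1 isolate whole and mixed those of the other. The 76 that mixed both isolates gave at most 2 genes. Counts so far above the real one point to a structure of the samples: a split of the first kind holds the whole treatment effect of 1 isolate. By the outcome set beforehand, 7 of 100 splits goes with a chance result, so chance is not excluded for the 7 genes. Because of that structure, these splits cannot tell chance from a difference between isolates. For the 912 genes changed the same way in both isolates, 1 of 100 splits, the real one, gave as many and the highest of the others gave 0. For the 1500 genes changed the same way by both inhibitors it was 1 of 60 splits, with a highest other of 18. An arbitrary labelling of the libraries therefore did not give such counts. Every other split drawn across the isolates mixed treated and control libraries in at least 1 isolate, so a low overlap was set in advance. Neither set of splits tests whether the overlap exceeds that of unrelated effects, and the second does not remove the part of the shared DMSO libraries.

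The 6 libraries of each remaining comparison make 10 splits, which are too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes as it did. The real counts are 1121 for KU60019 in isolate 1 (highest other 1), 2804 for KU60019 in isolate 4 (highest other 1), 2288 for KU55933 (highest other 0) and 112 between the inhibitors (highest other 0).

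KU60019 replicate 3 of isolate 4 lay at -80.6 on the second principal component, and a low depth is argued against by the 6 libraries with a lower total. A DMSO library of isolate 4 under its label is argued against by its mean log2 shift in the direction of KU60019 in isolate 1. That shift was 0.64, against 0.00 to 0.01 for DMSO of isolate 4. A library of isolate 1 is argued against by its correlations of 0.963 to 0.968 with isolate 4 groups and 0.936 to 0.944 with isolate 1 groups. Neither value tells KU60019 from KU55933, whose libraries had shifts of 0.51 to 0.56, and the correlation was 0.968 with both groups. A KU55933 library is argued against by CYP26B1. Its group, this library included, was at 5.52 ± 1.24 CPM, an SD that leaves no room for a library near the 46.4 ± 10.8 CPM with KU55933. Its deviation from its partners followed transcript length or GC content with a rank correlation of 0.65; another library reached 0.81, the outcome set as evidence against this trend, but a rank correlation carries no size and a trend elsewhere excludes none here, so this trend as a part of the distance cannot be told apart from other sources. In a second formulation chosen after that result, removing both trends took away 56% of the variance and left an SD of 0.41, against 0.13 to 0.19 in the 12 libraries of the other groups, which argues against them as the whole of the distance. RNA quality and library preparation may account for the rest and were not tested, nor was a biological explanation.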

How the results depend on the processing

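The fit without KU60019 replicate 3 in comparisons of other groups, in list members and in correlations was chosen only after the result was seen; the others were planned. No called list or named gene reversed its direction under any alternative run, but values that were not called crossed 0 in some, and the balance of higher and lower counts turned in 2 comparisons. With DESeq2 size factors in edgeR every count stayed within 1.5 times and medians shifted by at most 0.00403. Of the values of named genes, 515 of those without a filter, 508 of those with the replicate number as a block, 450 of those with only the compared groups and 3784 of those leaving out a library kept their side of the threshold. Those lost numbered 41, 50, 79 and 331, and those gained 2, 0, 21 and 53. The test recovered 38 to 49 of 100 genes changed 1.5-fold, so changes of that size are often missed at this depth and number of libraries.

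For KU60019 in isolate 1 the counts higher and lower were 320 and 334 without a filter, 282 and 351 with the block, 804 and 1048 with DESeq2, 1024 and 1176 with only the compared groups. Without a library they were 187 to 1546 and 203 to 2153. For KU60019 in isolate 4 they were 1129 and 895 without a filter, 2279 and 2161 without KU60019 replicate 1 and 1411 and 1389 without replicate 2, against 1386 and 1418; they were 131 and 155 with only the compared groups, and 656 to 2279 and 775 to 2161 leaving out a library. For KU55933 they were 3034 and 3235 with only the compared groups, and 574 to 2477 and 712 to 2648 leaving out a library. The order of the comparisons against DMSO thus depends on the fit. With only the compared groups, KU55933 had the most calls and KU60019 in isolate 4 the fewest. In the main fit KU60019 in isolate 4 had the most. For the difference between isolates the counts were 3 lower without a filter, 0 and 0 with the block, 12 and 20 with DESeq2, 0 and 0 with only the compared groups, against 777 at an unadjusted p under 0.05 in edgeR. Leaving out a library gave 0 to 11 and 0 to 22. For KU55933 against KU60019 they were 39 and 48 without a filter and 70 and 77 without KU60019 replicate 1, against 59 and 53, and 18 and 12 with the block, 221 and 195 with DESeq2, 3 and 3 with only the compared groups. The range over libraries left out was 15 to 177 and 9 to 152.

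Genes changed the same way in both isolates numbered 267 lower without a filter, 238 and 292 with the block, 617 and 842 with DESeq2, 243 and 341 with only the compared groups. Leaving out a library gave 167 to 1009 and 189 to 1366. For both inhibitors they numbered 534 lower without a filter, 379 and 496 with only the compared groups, and 339 to 1246 and 471 to 1560 leaving out a library. With an estimated correlation, 7, 5, 6, 0 and 1 lists were called for the comparisons in this order, and fry called 0 for the difference between isolates, against 2 with camera. Among the libraries left out, the highest gene counts came without KU60019 replicate 3 of isolate 4, or without replicate 1 for that group. Into KU60019 in isolate 1 and KU55933, KU60019 replicate 3 of isolate 4 enters only through the shared spread, the filter and the scaling. Without it the filter left 17614 genes against 17150, too few to hold the added calls. The replication medians were -0.71 and -0.55 without it, against -0.70 and -0.55. These values argue against the filter and the scaling as the main source of the rises there, which leaves the shared spread. The cause of the other changes was not tested. Same-numbered replicates showed no clear pairing, with r of -0.08 to 0.05 over 12 pairs. Yet 9 of 15 libraries correlated best with their own number, so a weak pairing is not excluded.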

Other observations

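No test in this part was chosen after the value it measures was seen, although both patterns were noticed in the data first. In isolate 4 single genes with endothelial functions were called, but not their lists: the Notch and sprouting list had adjusted p = 0.945 with KU60019 and 0.646 with KU55933, and the endothelial identity list 0.513 and 0.721. Camera looks for a shift in 1 direction, so members that move both ways can cancel out. The Notch and sprouting list had 6 higher and 6 lower of 24 members with KU60019, and 8 and 5 with KU55933. The endothelial identity list had 6 and 1 of 26, and 4 and 4. Of all genes, 16.3% and 13.3% were called with KU60019 and KU55933. In the Notch and angiogenic sprouting list, CXCR4, a chemokine receptor of sprouting cells, was higher with KU60019 (1.25 ± 0.08) and KU55933 (1.34 ± 0.08). ANGPT2, which encodes a secreted ligand of endothelial cells, was higher with both (0.78 ± 0.14 and 1.34 ± 0.14). APLN was lower with both (-1 ± 0.09 and -0.57 ± 0.09) and differed between them by 0.42 ± 0.09 (adjusted p = 0.0440). NOS3, which encodes endothelial nitric oxide synthase, was lower with KU55933 than with KU60019 (-0.57 ± 0.09, adjusted p = 0.0107), as was THBD (-0.47 ± 0.08, adjusted p = 0.0170).

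In the interferon list GBP1 was lower with KU60019 (-1.28 ± 0.12) and with KU55933 (-1.37 ± 0.12) in isolate 4, whereas ISG20 was higher (1.70 ± 0.20 and 1.64 ± 0.20). In the mitochondrial list CYCS, the gene of cytochrome c, was lower with both (-0.48 ± 0.08 and -0.62 ± 0.08), as was the coactivator gene PPARGC1B (-1.20 ± 0.24 and -1.44 ± 0.25). In the TGF-beta and BMP list BMP4 was lower with both (-1.04 ± 0.08 each). None of these 3 lists was called with either inhibitor in isolate 4 (adjusted p = 0.0717 or more), but without KU60019 replicate 3 the mitochondrial and TGF-beta lists were called with KU60019 (adjusted p = 0.00465 and 0.0187). The fry test called the TGF-beta list with KU60019 (adjusted p = 5.51e-04) and KU55933 (adjusted p = 0.00260) and the interferon list with KU55933 (adjusted p = 0.0426).

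The aryl hydrocarbon receptor targets CYP1A1, AHRR and TIPARP were higher with KU60019 in isolate 1 (2.38, 1.07 and 1.09) and in isolate 4 (1.95, 0.93 and 0.80), and with KU55933 (0.65, 0.74 and 0.88). A candidate explanation is activation of the receptor by KU60019, which requires a rise of the further target CYP1B1. CYP1B1 was higher by 3.97 ± 0.62 in isolate 1 (adjusted p = 0.00200) and by 2.58 ± 0.51 in isolate 4 (adjusted p = 0.00439), at levels of 0.0413 to 0.923 CPM that are close to the floor. Whether the rise depends on the receptor, on ATM or on the compound apart from ATM stays open. AHRR, TIPARP, CYP1B1, RARB and TGM2 lie outside the rule for named genes.

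The retinoic acid targets CYP26B1, DHRS3 and RARB were higher with KU55933 than with KU60019 (3.07, 1.33 and 0.87). Against DMSO, KU55933 raised CYP26B1 (1.83) and DHRS3 (0.81), but RARB was not called (0.22, adjusted p = 0.29). KU60019 lowered CYP26B1 (-1.24) and RARB (-0.65, adjusted p = 0.0038), and DHRS3 was not called (-0.51, adjusted p = 0.0945). A candidate explanation is more retinoic acid signalling with KU55933 than with KU60019. Of 9 further targets fixed before their values were looked at, 6 could be tested. Their median difference was 0.02 and 0 of them were called, where the explanation requires a median above 0 and at least 1 called higher. TGM2, at 1340 ± 37.9 and 1360 ± 34.7 CPM, differed by -0.02 ± 0.07, and several others were below 1 CPM. Against DMSO, TGM2 was called lower with KU55933 (-0.51) and with KU60019 (-0.49). With neither outcome set beforehand met in full, this explanation cannot be told apart from a change of these 3 genes alone.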
